A study of Mus musculus with 12 samples.

How the data were processed

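RNA of 12 samples of cultured mouse aortic smooth muscle cells, 6 at 0.3 g/l and 6 at 4.5 g/l glucose, was measured on an Affymetrix mouse whole-transcript gene array. Per the labels' protocols, total RNA was extracted with a kit, fragmented by enzymes and labelled with biotin. The authors deposited 1 table of log2 values per probe set and sample; per the submitters' processing notes it was made with Affymetrix Expression Console and RMA, which corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. No version, scan date, detection call or genome build was given in the sources used here, so no coordinates are given and no batch was known. The log2 scale was read from the values, which ran from 0.60 to 13.90 with none missing. RMA with quantile normalization makes array distributions alike, so a change in total RNA per cell cannot be seen, and it compresses differences of dim genes.

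The table held 41345 probe sets. The platform annotation used here listed genes for 25335 of them: 23521 had 1 gene symbol, 1814 had several and were not named, and 16010 were unnamed here. Each of the 22180 genes was represented by the probe set with the highest mean over all 12 arrays, a choice that mattered for the 1082 genes with more than 1. The groups were those of the sample labels. No columns were identical; correlations between arrays ran from 0.979 to 0.990 within 0.3 g/l and from 0.982 to 0.990 within 4.5 g/l.

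Values were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, without a block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Genes changed at least 1.5-fold were also counted. Gene lists written before the data were examined were tested with camera in the same model, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 42 lists with at least 5 measured members. Of 903 list entries, 814 were matched by symbol or Entrez ID. The result of 1 of the lists is not reported here. Camera compares a list with all other genes, and it was repeated with the correlation estimated from the data. The fit for this comparison was tested on simulated data with 22180 genes, of which 50 each were changed by log2 0.5, 1, 2 and 3. Of these, 78%, 94%, 100% and 100% were recovered, and 10 of 196 calls were of unchanged genes. These rates describe the simulated data only. In the measured data an array stood apart from its group, and members of some lists were strongly correlated. The rates of recovery and of false calls may therefore differ there. Figures were drawn with matplotlib 3.10.9.

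The named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among changed genes, leaving out predicted or unnamed genes, small RNAs and olfactory or vomeronasal receptors; the 4 changed members with the smallest p of each primary list (contractile, actin under SRF and MRTF, MondoA and ChREBP, ATF4, unfolded protein response, glycolysis) and of each other list past the camera threshold; and always Myh11, Acta2, Tagln, Cnn1, Smtn, Myocd, Srf, Mrtfa, Klf4, Txnip, Slc2a1, Hk2, Hspa5 and Asns. This gave 97 genes. Cdh5 and Emcn, and genes of the closing section, were named after their values were seen.

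Alternatives fixed before the data were examined were a mean-variance trend with robust moderation, leaving out the lowest 25% of genes by mean (below 4.20), quantile normalization, cyclic loess or median centring of the arrays, the mean of a gene's probe sets, all probe sets, array weights, the replicate number as a block, an exact rank-sum test, a test against a fold of 1.2 and leaving out each array in turn; for lists also an estimated correlation, camera on ranks and fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. Alternatives chosen after seeing the data were replicates 1 to 3 or 4 to 6 alone (the latter also without 0.3 g/l replicate 4) or as a block, and the estimated correlation without 0.3 g/l replicate 4 or within replicates 1 to 3. Arrays give no read depth; their number limits the precision, and the median SE of a log2 difference was 0.0931.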

Results

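Gene expression was measured by microarray in primary smooth muscle cells from the aorta of C57BL/6J mice, an inbred laboratory strain. The cells were at passage 3 to 4, in DMEM with 10% fetal calf serum, at a glucose concentration of either 0.3 g/l (1.7 mM) or 4.5 g/l (25 mM). The labels disagree on how long: the series text gives 14 days and the sample labels give 1 week. Each group held 6 arrays, numbered as replicates 1 to 6. The labels do not say whether these came from separate cultures or animals, so all p-values here measure the spread between these samples, which may be technical. An osmotic control was not analysed here. The question was how the glucose level alters expression in vascular smooth muscle cells in culture. All values are log2 RMA values; the median over all probe sets lay between 4.92 and 5.05 on the 12 arrays, and the number of arrays limits the precision.

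The first principal component of 22180 genes held 46.2% of the variance and parted the groups by 39.7 units, against a within-group SD of 13.8 (two-sided exact permutation test over 924 assignments, p = 0.00866; the smallest p possible was 0.00216). Apart from replicate 4, the 0.3 g/l arrays lay between -30.2 and -24.4, and the 4.5 g/l arrays between 12.5 and 26.2. Replicate 4 of the 0.3 g/l group lay at 17.2, among the 4.5 g/l arrays. Its highest correlation was 0.982 with an array of its own group and 0.985 with a 4.5 g/l array. On the second component (10.9%), 4.5 g/l replicates 1 to 3 lay between -17.9 and -12.0 and replicates 4 to 6 between 12.6 and 16.1. All 12 arrays were kept in the comparison.

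**Figure D1:**
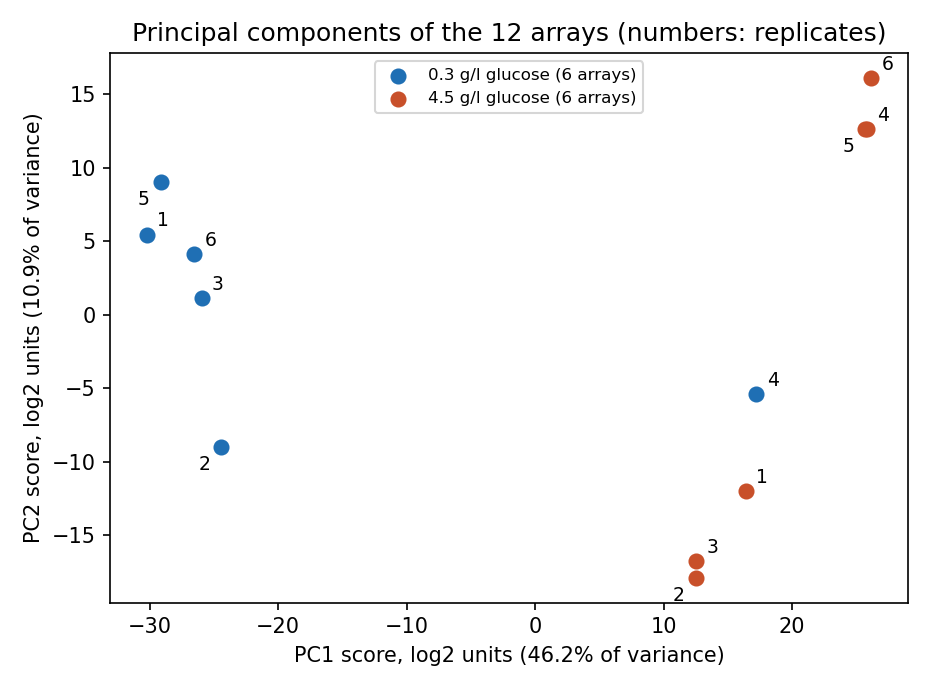
Scores of the 12 arrays on the first (x axis) and second (y axis) principal components of the log2 values, with each point 1 array, its colour the glucose group and its number the replicate. Replicate 4 of the 0.3 g/l group lies at 17.2 on the first component, within the 12.5 to 26.2 of the 4.5 g/l arrays, and the 4.5 g/l arrays part into replicates 1 to 3 and 4 to 6 on the second.

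Contractile and actin genes of smooth muscle were higher in 4.5 g/l glucose, and genes of the amino acid response and of endoplasmic reticulum stress were lower. Of the contractile list 19 of 24 rose, of the actin list 27 of 30, and 31 of 33 amino acid response and 22 of 22 unfolded protein response genes fell. With an estimated correlation none of these 4 lists passed in camera (adjusted p = 0.177 for the first 3 and 0.301 for the last). The 10 largest rises among named genes ran from Tgfb3, a growth factor of the TGF-beta family (4.84-fold), to Aoc3, a vascular amine oxidase (15.0-fold), with the smooth muscle myosin heavy chain Myh11 at 9.07-fold and the thioredoxin-binding protein Txnip at 9.32-fold (a log2 difference of 3.22, and of 3.82 without 0.3 g/l replicate 4). The 10 largest falls ran from the cystine transporter subunit Slc7a11 (4.21-fold lower in 4.5 g/l) to the phosphatase Ppef1 (5.77-fold lower), and included the stress transcription factor Ddit3 and the interferon-induced Usp18 and Ifit1. Aoc3 had a mean log2 value of 4.51 in 0.3 g/l and Ppef1 of 4.58 in 4.5 g/l. Both are close to the 4.20 below which the dimmest 25% of genes lay, so their folds are uncertain. In limma with Benjamini-Hochberg adjustment, 3444 of 22180 genes (15.5%) passed an adjusted p of 0.05, with 1555 higher and 1889 lower in 4.5 g/l. The excess of lower genes depended on scaling, with 1745 higher and 1722 lower after cyclic loess, 1712 and 1778 after quantile normalization, and 1512 and 1606 with median centring. Of the 3444 genes, 864 changed at least 1.5-fold, 425 upward and 439 downward. The groups did not overlap in 1327 of the changed genes. Over all tested genes 1419 did not overlap, where chance would give 0.216%, or 48.0 genes. Without 0.3 g/l replicate 4, 5295 genes passed (2288 higher, 3007 lower). After seeing the split among the 4.5 g/l arrays, the comparison was repeated within replicates 1 to 3, where 2900 genes passed, within replicates 4 to 6, where 30 passed, or 3435 with 0.3 g/l replicate 4 left out, and over all arrays with those number ranges as a block, where 3887 passed.

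Smooth muscle contractile genes rose together. Of 24 measured members, 19 rose and 5 did not pass (20 rose when adjusted over the list alone), with a median log2 difference of 1.14. Myh11 rose from 7.40 ± 0.69 to 10.58 ± 0.23 (log2, mean ± SD, n = 6; probe set 17328368; limma adjusted p = 1.22e-05). Kcnmb1, the beta subunit of the large-conductance potassium channel, rose by 2.36 ± 0.17 (log2 difference ± SE), the actin-binding Synpo2 by 2.51 ± 0.19 and calponin, Cnn1, by 2.82 ± 0.45. The smooth muscle gamma actin Actg2 rose 8.67-fold. Acta2, smooth muscle alpha actin, rose 1.60-fold to 13.83 ± 0.06 (n = 6), Tagln 1.84-fold, Smtn 2.24-fold and Csrp1 2.05-fold. As probe sets of closely related actins can share signal, values of single actin genes are uncertain. The list's camera adjusted p was 8.42e-22, and the adjusted p was 0.177 with an estimated correlation and 0.0150 with an estimated correlation and 0.3 g/l replicate 4 left out. The other 5 arrays of 0.3 g/l had list means of 8.09 to 8.26 and the 4.5 g/l arrays 9.53 to 9.75, with replicate 4 of the 0.3 g/l group between them at 9.15.

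Actin cytoskeleton genes controlled by the transcription factor SRF and its MRTF cofactors rose in 27 of 30 members, and 3 did not pass (29 rose when adjusted over the list alone; median log2 difference 0.65). The fibronectin receptor subunit Itga5 rose 3.18-fold, the actin-depolymerising factor Dstn 1.88-fold, the crosslinker Flna 1.95-fold and Tagln2 1.53-fold. Camera gave an adjusted p of 3.68e-26 for this list, and the adjusted p was 0.177 with an estimated correlation, and 0.0150 with that and 0.3 g/l replicate 4 left out. Srf itself rose 1.63-fold (limma adjusted p = 0.00729). Myocd, the smooth muscle cofactor of SRF, differed by 0.20 ± 0.09 (SE, limma adjusted p = 0.141) and Mrtfa by 0.44 ± 0.16 (limma adjusted p = 0.0840). With 12 arrays neither passed, and both passed without 0.3 g/l replicate 4 (0.28 and 0.58). Within replicates 1 to 3, with fewer arrays, neither passed (0.20 and 0.27, limma adjusted p = 0.135 and 0.0691). Mrtfa lay at 7.85 to 7.96 in 4.5 g/l replicates 1 to 3 and at 8.33 to 8.42 in replicates 4 to 6. The size of its difference thus depended on the 4.5 g/l arrays used. Klf4, a transcription factor known to repress contractile genes, fell by 1.52 ± 0.22 on the log2 scale (limma adjusted p = 0.000677).

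**Figure D2:**
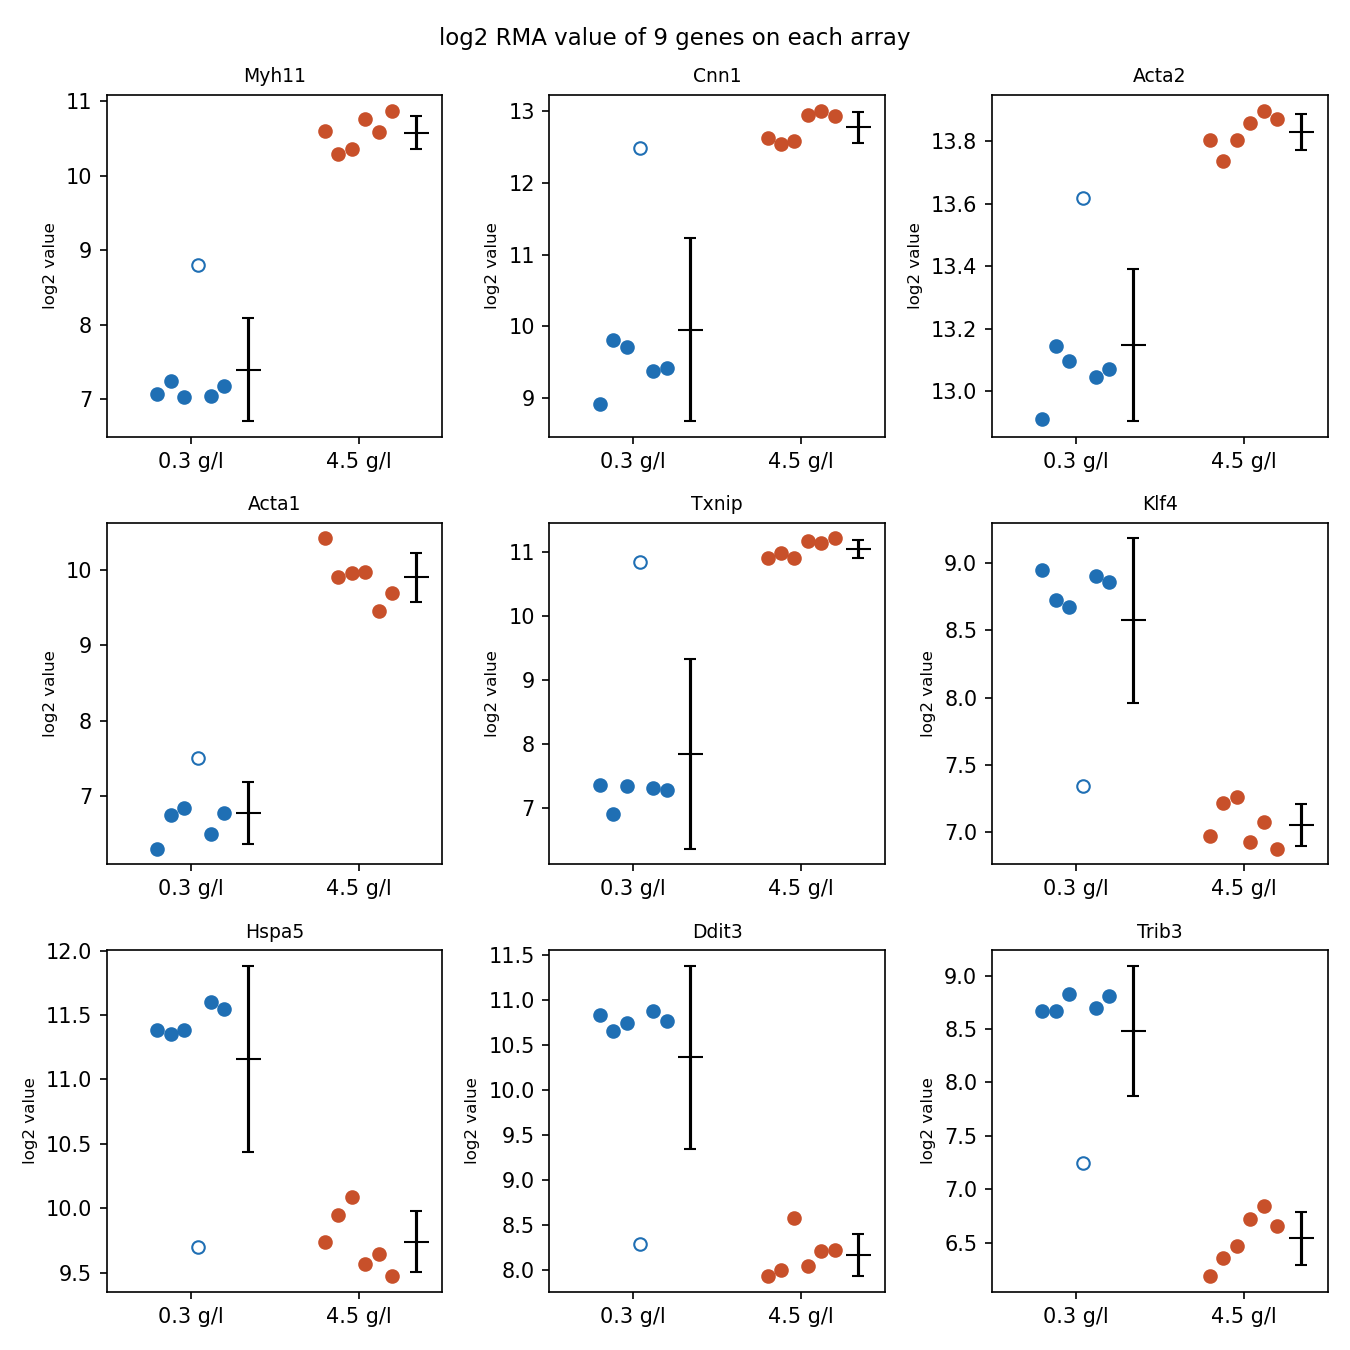
The log2 RMA value (y axis) of 9 genes on each of the 12 arrays by glucose group (x axis), with points ordered by replicate number, the bar and whiskers giving mean ± SD (n = 6), and an open point for 0.3 g/l replicate 4. Myh11 lies between 10.29 and 10.87 in 4.5 g/l and at 8.80 in 0.3 g/l replicate 4, while Txnip in that array, 10.85, is close to the lowest 4.5 g/l value, 10.90.

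ATF4 and amino acid response genes, induced when amino acids run short, were lower in 4.5 g/l. Of 33 members, 31 fell and 2 did not pass (32 fell when adjusted over the list alone), with a median log2 difference of -0.93. Cth, an enzyme of cysteine synthesis, fell by 2.37 ± 0.31 on the log2 scale (SE) and Trib3, a pseudokinase, fell by 1.95 ± 0.23. The arginine transporter Slc7a1 was 1.91-fold lower, the stress-induced Sesn2 1.57-fold lower and asparagine synthetase, Asns, 1.88-fold lower. Asns lay at 9.83 to 9.97 in 4.5 g/l replicates 1 to 3 and at 10.52 to 10.64 in replicates 4 to 6. It lay at 10.69 in 0.3 g/l replicate 4. Its log2 difference was -1.33 within replicates 1 to 3. Within replicates 4 to 6, that array included, it was -0.50 and did not pass (limma adjusted p = 0.220). The adjusted p in camera was 5.88e-26, and the adjusted p was 0.177 with an estimated correlation and 0.0150 with that and 0.3 g/l replicate 4 left out. List means were 9.47 to 9.50 in the 5 arrays of 0.3 g/l other than replicate 4, 8.56 in 0.3 g/l replicate 4 and 8.11 to 8.42 in the 4.5 g/l arrays.

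All 22 measured unfolded protein response genes fell (22 also when adjusted over the list alone), with a median log2 difference of -0.90. The endoplasmic reticulum chaperone Hspa5 fell from 11.16 ± 0.72 to 9.74 ± 0.24 (n = 6; probe set 17370103; limma adjusted p = 0.00308). Herpud1 was 2.54-fold lower, the co-chaperone Dnajb9 2.47-fold, the transcription factor Xbp1 1.52-fold, the ubiquitin ligase Syvn1 1.58-fold and Sdf2l1 5.26-fold. Derl3, which is not a member of this list and was named for its large fall, was 4.37-fold lower. Camera gave an adjusted p of 7.01e-17, and the adjusted p was 0.301 with an estimated correlation and 0.0150 with that and 0.3 g/l replicate 4 left out. That array had a list mean of 9.50, within the 9.48 to 9.70 of the 4.5 g/l arrays, where the other 5 arrays of 0.3 g/l had 10.71 to 10.79. The exact rank-sum test passed 4 of the 22 genes. The 4 lowest list means, of 0.3 g/l replicate 4 and 4.5 g/l replicates 4 to 6, were those of the 4 arrays with the lowest means of endothelial markers.

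Genes of glucose handling moved in different directions. Txnip, the best known target of the glucose-sensing factors MondoA and ChREBP, rose from 7.84 ± 1.48 to 11.06 ± 0.14 (n = 6; probe set 17400599; limma adjusted p = 0.00116), a log2 difference of 3.22 that was 3.82 without 0.3 g/l replicate 4, and its relative Arrdc4 rose 1.87-fold. Acaca and Acacb, the acetyl-CoA carboxylases, were 1.28-fold and 1.30-fold lower. Over that list 3 of 19 genes rose and 2 fell (3 and 3 adjusted over the list alone; 2 passed in the rank-sum test), and it did not pass (camera adjusted p = 0.588). Of 21 glycolysis and glucose transport genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone). The phosphofructokinases Pfkp and Pfkl rose 1.70-fold and 1.32-fold and lactate dehydrogenase Ldha 1.30-fold, whereas hexokinase 2, Hk2, was 2.12-fold lower and the lactate transporter Slc16a1 1.85-fold lower. The glucose transporter Slc2a1 differed by -0.27 ± 0.13 and did not pass with 12 arrays (limma adjusted p = 0.188). It passed without 0.3 g/l replicate 4 (-0.39, limma adjusted p = 0.00555), but not within replicates 1 to 3 (-0.21, limma adjusted p = 0.0998). Slc2a1 lay at 10.38 to 10.44 in 4.5 g/l replicates 1 to 3 and at 9.97 to 10.10 in replicates 4 to 6. The camera adjusted p of glycolysis was 0.0157, and the adjusted p was 0.435 with an estimated correlation, and 0.236 without 0.3 g/l replicate 4. Polyol, hexosamine and pentose phosphate genes fell in 5 of 13 (7 adjusted over the list alone; 2 passed in the rank-sum test), among them the hexosamine enzymes Gnpnat1 (1.80-fold lower), Pgm3 (1.2-fold) and Gfpt2 (1.43-fold) and the pentose phosphate enzyme Pgls (1.22-fold); camera gave an adjusted p of 0.00340, and the adjusted p was 0.348 with an estimated correlation, 0.0248 with that and 0.3 g/l replicate 4 left out, and 0.0770 within replicates 4 to 6. In cholesterol synthesis, 5 of 19 rose and 1 fell (7 and 1 adjusted over the list alone; 3 passed in the rank-sum test): Hmgcs1 rose 1.60-fold, Hsd17b7 1.56-fold and Nsdhl 1.35-fold, and the sterol-regulated Insig1 was 1.40-fold lower. Its camera adjusted p was 0.0254, and the adjusted p was 0.348 with an estimated correlation, and the list no longer passed without 0.3 g/l replicate 4 (0.0674), 4.5 g/l replicate 4 (0.0580) or 4.5 g/l replicate 6 (0.0558), with array weights (0.0689), on ranks (0.0552) or within replicates 1 to 3 (0.407).

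Cell division genes were higher in 4.5 g/l. In the mitosis list 27 of 29 rose (28 rose when adjusted over the list alone; median log2 difference 0.52). Anln, an actin-binding protein of the cleavage furrow, rose 2.15-fold, the spindle protein Prc1 1.52-fold, topoisomerase Top2a 1.5-fold and the kinase Ttk 1.41-fold. The adjusted p in camera was 3.35e-23, and the adjusted p was 0.177 with an estimated correlation, 0.0570 with that and 0.3 g/l replicate 4 left out, and 0.0420 with that within replicates 1 to 3. In DNA replication 14 of 27 genes rose (14 rose and 1 fell when adjusted over the list alone), with the helicase subunits Mcm6 at 1.62-fold, Mcm4 at 1.5-fold, Mcm5 at 1.37-fold and Mcm3 at 1.29-fold. With all 12 arrays this was the one list of the 42 written beforehand to pass both ways (camera adjusted p = 7.16e-08, and adjusted p = 0.0339 with an estimated correlation). With an estimated correlation its adjusted p was 0.0555 without 0.3 g/l replicate 4 and 0.196 within replicates 1 to 3. Mitosis list means were 7.78 to 7.84 in the 5 arrays of 0.3 g/l other than replicate 4, 8.13 in 0.3 g/l replicate 4, 8.44 to 8.47 in 4.5 g/l replicates 1 to 3 and 8.25 to 8.32 in replicates 4 to 6.

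Interferon response genes fell in 12 of 22 members (14 fell when adjusted over the list alone; median log2 difference -0.58). Ifit1 was 4.97-fold lower, Oasl2 3.05-fold, Mx2 2.52-fold and Rsad2 1.45-fold. Mx2 had a mean log2 value of 3.73 in 4.5 g/l, below the 4.20 that bounds the dimmest 25% of genes, and Rsad2 of 4.41, so their folds are uncertain. Camera gave an adjusted p of 1.48e-06, and the adjusted p was 0.348 with an estimated correlation. List means were 6.53 to 6.70 in the 5 arrays of 0.3 g/l other than replicate 4, 5.76 to 5.88 in 4.5 g/l replicates 1 to 3, and 5.23 to 5.30 in 4.5 g/l replicates 4 to 6, with 5.32 in 0.3 g/l replicate 4. Those last 4 arrays also had the lowest means of endothelial markers, 6.72 to 6.79 and 6.99, against 7.33 to 7.51 in the others. The exact rank-sum test passed 0 of the 22 genes, where limma passed 12 and gave 14 an unadjusted p under 0.05.

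Some extracellular matrix and TGF-beta genes rose, while most members of each list did not. Of 28 fibrillar collagen and matrix genes, 9 rose (12 rose when adjusted over the list alone; 2 passed in the rank-sum test), including Col15a1 (2.31-fold), Col3a1 (1.76-fold), Col6a2 (1.52-fold) and Col8a1 (1.46-fold); camera gave an adjusted p of 1.23e-06, and the adjusted p was 0.348 with an estimated correlation. Of 15 basement membrane genes, 6 rose and 2 fell (9 and 3 adjusted over the list alone; 4 passed in the rank-sum test): Col18a1 rose 1.82-fold, Col4a1 1.70-fold and Nid1 1.41-fold, and the laminin chain Lama2 was 1.64-fold lower. The adjusted p in camera was 0.00977, and the adjusted p was 0.282 with an estimated correlation and 0.101 within replicates 1 to 3. Of 23 genes of the TGF-beta and BMP pathway 7 rose (7 adjusted over the list alone; 3 passed in the rank-sum test), with Tgfb3 up 4.84-fold, its binding protein Ltbp1 1.71-fold, the pseudoreceptor Bambi 1.92-fold and Id2 1.41-fold. The camera adjusted p was 0.0157, and the adjusted p was 0.348 with an estimated correlation and 0.0994 in camera on ranks. For the fibrillar collagen list 0.3 g/l replicate 4 had the highest mean of the 12 arrays, 10.17, against 9.59 to 9.79 in the rest of its group and 10.04 to 10.14 in 4.5 g/l.

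Some lysosome, antioxidant and ribosomal protein genes fell, and most members of these lists did not pass. Of 29 lysosome and autophagy genes, 13 fell (19 fell and 1 rose when adjusted over the list alone, and 2 passed in the rank-sum test); the autophagy receptor Sqstm1 was 1.83-fold lower, the lysosomal channel Mcoln1 1.78-fold, the cholesterol exporter Npc1 1.52-fold and the transcription factor Tfe3 1.26-fold. Camera gave an adjusted p of 2.83e-07, and the adjusted p was 0.362 with an estimated correlation. NRF2 antioxidant genes fell in 7 of 19 and 1 rose (9 and 1 adjusted over the list alone, and 2 passed in the rank-sum test), with heme oxygenase Hmox1 2.63-fold lower, Slc7a11 4.21-fold, Gclm 1.5-fold and Osgin1 1.38-fold. The camera adjusted p was 9.63e-05, and the adjusted p was 0.362 with an estimated correlation. Ribosomal protein genes fell in 11 of 30 (14 adjusted over the list alone), by little: Rpl32 was 1.34-fold lower, Rps3 1.23-fold, Rplp1 1.21-fold and Rpl19 1.18-fold. The adjusted p in camera was 1.20e-07, and the adjusted p was 0.301 with an estimated correlation. In 0.3 g/l replicate 4 the lysosome and NRF2 list means were 9.64 and 9.00, against 9.65 to 9.82 and 9.00 to 9.26 in the 4.5 g/l arrays. Both lists had their 4 lowest means in that array and 4.5 g/l replicates 4 to 6, as did endothelial markers.

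**Figure D3:**
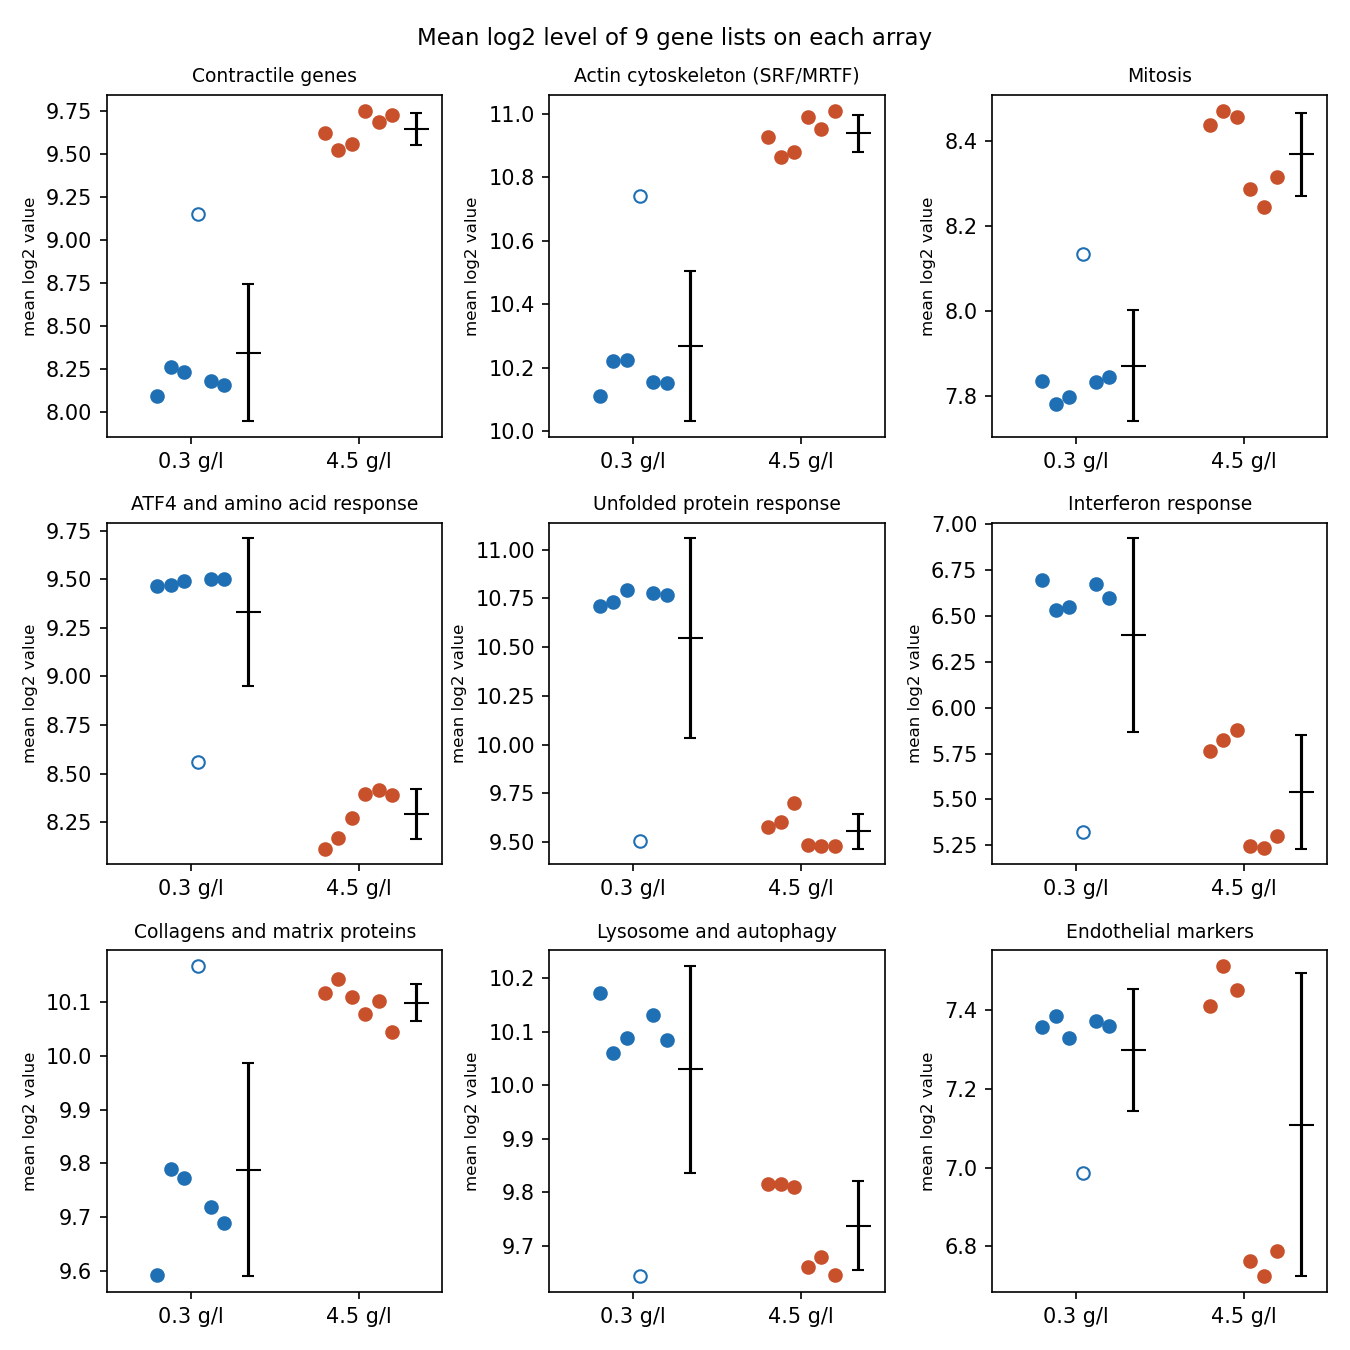
Mean log2 value over the members of 9 gene lists (y axis) on each of the 12 arrays by glucose group (x axis), with points ordered by replicate number, the bar and whiskers giving mean ± SD (n = 6), and an open point for 0.3 g/l replicate 4. The endothelial panel shows 4.5 g/l replicates 4 to 6 at 6.72 to 6.79, below the 7.41 to 7.51 of replicates 1 to 3.

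Probe sets named for microRNA genes rose in 31 and fell in 7 of 484 (23 and 5 adjusted over the list alone, and 19 passed in the rank-sum test; camera adjusted p = 0.0157, and adjusted p = 0.414 with an estimated correlation, 0.0956 in fry and 0.0983 within replicates 1 to 3). Mir145a, from a locus active in smooth muscle, rose 6.48-fold, Mir23b 2.16-fold, Mir193a 1.60-fold and Mir181b-2 1.51-fold, with the last 2 at low log2 values of 4.14 and 4.38 in 0.3 g/l; these probe sets do not part mature from precursor RNA. Striated muscle markers passed in camera on Acta1, skeletal alpha actin (8.72-fold higher), and Actc1, cardiac alpha actin (1.41-fold higher, at low log2 values of 4.27 and 4.77), while 14 of 16 members did not pass (2 rose when adjusted over the list alone). Their camera adjusted p was 0.0445, and the adjusted p was 0.436 with an estimated correlation. The list no longer passed without 0.3 g/l replicate 1 (0.0993), 5 (0.0579) or 6 (0.0805), or without 4.5 g/l replicate 2 (0.0557), 3 (0.0560) or 6 (0.0576). It also lost its call without the lowest 25% of genes (0.0676), after quantile normalization (0.0738) or cyclic loess (0.0721), in camera on ranks (0.103), within replicates 1 to 3 (0.0767) and within replicates 4 to 6 (0.0859).

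Endothelial markers fell in 1 of 16 members (1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.137). It passed, lower in 4.5 g/l, without 4.5 g/l replicate 1 (0.0344), 2 (0.0165) or 3 (0.0302), within replicates 4 to 6 (2.27e-08), within those with 0.3 g/l replicate 4 left out (2.03e-08), and with the replicate block (0.0481). List means were 7.33 to 7.39 in the 5 arrays of 0.3 g/l other than replicate 4 and 7.41 to 7.51 in 4.5 g/l replicates 1 to 3, against 6.99 in 0.3 g/l replicate 4 and 6.72 to 6.79 in 4.5 g/l replicates 4 to 6. Cdh5 and Emcn, genes of endothelial cells, had log2 values of 11.10 and 11.71 in 0.3 g/l and of 10.51 and 11.28 in 4.5 g/l. Macrophage markers passed in limma in 0 of 16 (1 at an unadjusted p under 0.05, 0 by the rank-sum test; 0 adjusted over the list alone; camera adjusted p = 0.891). Adventitial fibroblast markers rose in 2 and fell in 1 of 14 (3 and 2 adjusted over the list alone; camera adjusted p = 0.716).

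**Figure D4:**
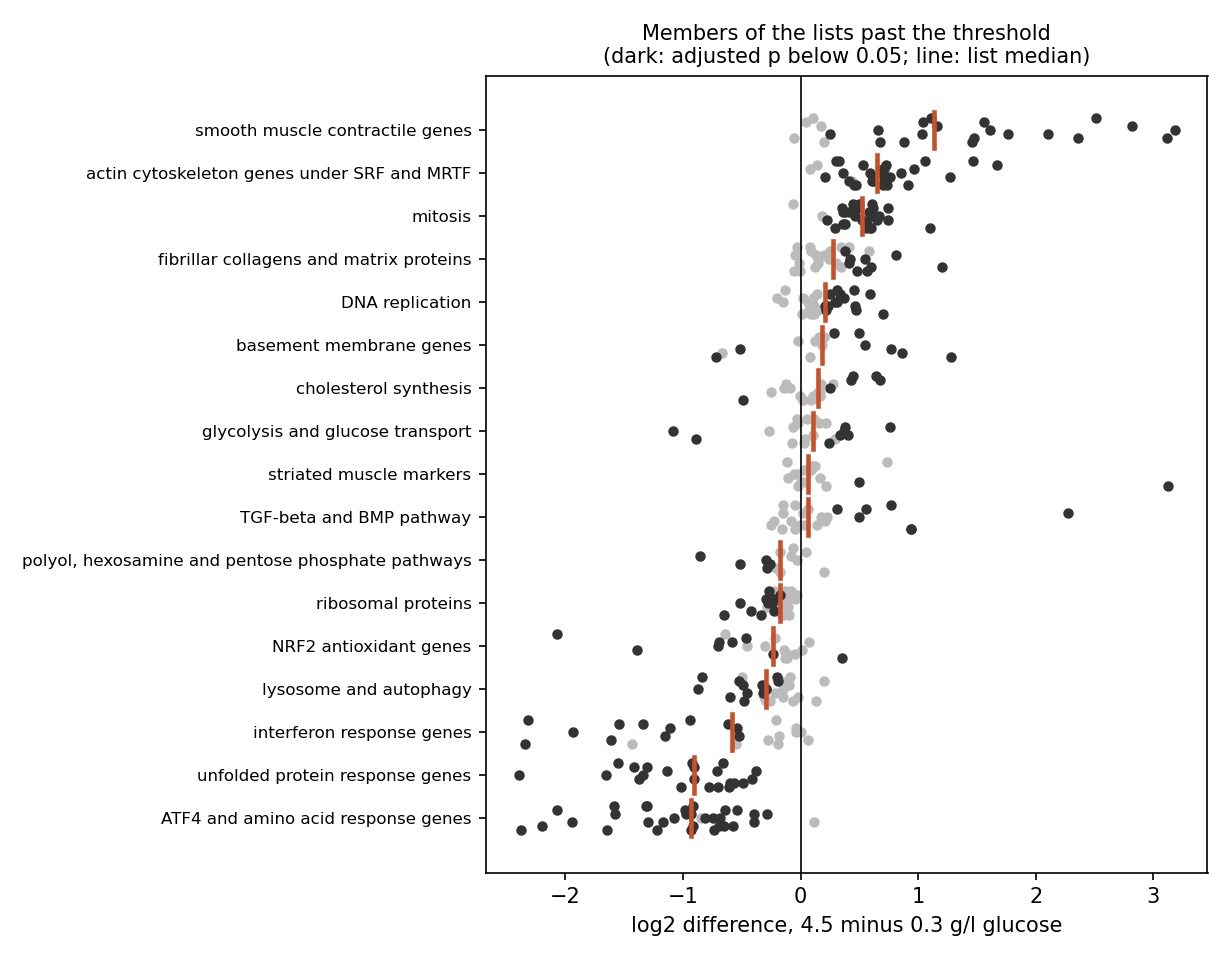
The log2 difference, 4.5 minus 0.3 g/l glucose (x axis), of each measured member of 17 lists past the camera threshold (y axis; the microRNA genes are not drawn), dark where the gene itself passed in limma, with a line at the list median. All 22 unfolded protein response genes lie below 0, and the contractile median lies at 1.14.

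Of 42 lists tested, 18 passed in camera, 11 higher and 7 lower in 4.5 g/l, and 1 passed with an estimated correlation. Nuclear oxidative phosphorylation genes rose in 1 and fell in 1 of 30 (0 and 1 adjusted over the list alone; camera adjusted p = 0.814), and fatty acid oxidation and PPAR genes rose in 3 and fell in 2 of 25 (6 and 4 adjusted over the list alone; adjusted p = 0.449). Of 17 tricarboxylic acid cycle genes 0 passed in limma (3 at an unadjusted p under 0.05, 0 by the rank-sum test; 0 adjusted over the list alone; camera adjusted p = 0.588). HIF targets rose in 2 and fell in 1 of 18 (2 and 1 adjusted over the list alone; 0.961), p53 targets rose in 3 and fell in 5 of 17 (3 and 5; 0.281), and inflammatory and NF-kB genes rose in 2 and fell in 3 of 26 (3 and 6; 0.692). Smooth muscle phenotype regulators rose in 6 and fell in 4 of 29 (8 and 6 adjusted over the list alone; camera adjusted p = 0.588), osteochondrogenic genes rose in 2 and fell in 2 of 18 (2 and 2; 0.588), and vascular ion channels and receptors rose in 3 and fell in 1 of 22 (3 and 2; 0.445). Matrix proteases and inhibitors rose in 4 and fell in 3 of 21 (6 and 3 adjusted over the list alone; camera adjusted p = 0.106), and 1 of 13 genes of a cholesterol-loaded macrophage-like state fell (1; 0.281, and 0.00646 within replicates 4 to 6 with 0.3 g/l replicate 4 left out). For reported lists not past the camera threshold whose counts are not given elsewhere, the rank-sum test passed 7 immediate early genes, 6 fatty acid oxidation and PPAR genes, 5 inflammatory genes, 3 oxidative phosphorylation genes and 3 adventitial fibroblast markers. It also passed 4 p53 targets, 4 matrix proteases and inhibitors, 4 heat shock genes, 3 phenotype regulators, 3 small RNA genes, 2 ion channels and receptors, and 1 each of HIF targets and osteochondrogenic, adipocyte, neural and epithelial genes. It passed 0 endothelial markers and 0 genes of the macrophage-like state (3 of each at an unadjusted p under 0.05 in limma).

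Immediate early genes rose in 6 and fell in 3 of 23 (9 and 3 adjusted over the list alone); their camera adjusted p was 0.0527, and 0.00225 without 0.3 g/l replicate 4 or 0.0376 without 4.5 g/l replicate 1. This list also passed with median centring (0.0452), array weights (0.00652), the replicate block (0.0322), camera on ranks (0.0446), the block of number ranges (0.0444), within replicates 1 to 3 (0.00826), within replicates 4 to 6 with 0.3 g/l replicate 4 left out (0.00426), and with an estimated correlation and 0.3 g/l replicate 4 left out (0.0321). Heat shock genes rose in 5 and fell in 3 of 14 (5 and 3 adjusted over the list alone; camera adjusted p = 0.264, and 0.0104 in fry). Small RNA genes rose in 2 and fell in 8 of 84 (2 and 7 adjusted over the list alone); their camera adjusted p was 0.148, and 0.0468 without 0.3 g/l replicate 1 or 0.0439 without 4.5 g/l replicate 1, 0.00552 within replicates 4 to 6 and 0.0349 within those with 0.3 g/l replicate 4 left out. Of 10 mitochondrially encoded genes 0 passed in limma (0 at an unadjusted p under 0.05, 0 by the rank-sum test; 0 adjusted over the list alone; camera adjusted p = 0.557), and of 9 lymphocyte markers 0 passed (1 and 0 likewise; 0 adjusted over the list alone; 0.639). Adipocyte markers fell in 1 of 11 (1 adjusted over the list alone; camera adjusted p = 0.827), neural and Schwann cell markers fell in 2 of 9 (2; 0.445), and epithelial and mesothelial markers rose in 1 and fell in 1 of 11 (1 and 1; 0.439). Erythroid markers had 2 measured members and were not tested. The median and mean log2 difference differed in sign for fatty acid oxidation genes, phenotype regulators, inflammatory genes, and macrophage, adventitial fibroblast and adipocyte markers. The median also opposed the direction of camera for the inflammatory, macrophage, fibroblast and adipocyte lists.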

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

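The tests of a wrong label, of mixed RNA, of endothelial cell share, of other cell types and of normalization were chosen only after the results they bear on were seen; the count over other splits was planned. In groups of 6 arrays, the gap between the extreme array and its nearest neighbour was divided by the range of the group and set against Dixon's critical value. Of 280 groups tested, 83 passed (29.6%), where chance would give about 14, and in 79 of the 83 the extreme array was 0.3 g/l replicate 4. These were 61 of the 63 genes, 17 of the 19 list means and the first principal component, with a ratio of 0.88. The ratio was 0.95 for Herpud1, 0.93 for Sdf2l1, 0.92 for Cth, Usp18 and Ifit1, 0.91 for Ddit3. It was 0.90 for Trib3, Mcoln1 and Slc2a1, 0.89 for Txnip, Dnajb9 and Slc16a1, 0.88 for Myh11, Slc7a11 and Hk2, 0.87 for Rsad2 and Hspa5. The gap-to-range ratio was 0.86 for Apol9b, Hmox1, Bambi and Sqstm1, 0.85 for Actg2 and Tgfb3, 0.83 for Acaca, Col6a2, Npc1, Smtn and Klf4, 0.81 for Col4a1 and Srf. Among further genes it was 0.80 for Aoc3 and Derl3, 0.79 for Sh3bgr, 0.78 for Gnpnat1, 0.77 for Kcnmb1, Dstn and Oasl2. The ratio was 0.76 for Capn6, Csrp1, Hmgcs1 and Anln, 0.75 for Cnn1, Synpo2, Ppef1, Gars, Mir145a and Asns, 0.74 for Flna, 0.72 for Mcm4, Myocd and Mrtfa. It was 0.71 for Gclm, 0.68 for Nsdhl, 0.67 for Slc7a1, Osgin1, Col8a1 and Acta2, 0.66 for Xbp1 and Prc1. The gap-to-range ratio was 0.64 for Syvn1 and Mir23b. For the means of gene lists the ratio was 0.96 for ATF4 and amino acid response genes, 0.94 for unfolded protein response genes, 0.88 for interferon response genes, 0.86 for endothelial markers. Further list means had ratios of 0.85 for immediate early genes, 0.84 for smooth muscle contractile genes, 0.83 for cholesterol-loaded macrophage-like state, 0.82 for actin cytoskeleton genes under SRF and MRTF and mitosis. Others had 0.80 for NRF2 antioxidant genes, 0.79 for lysosome and autophagy, 0.78 for TGF-beta and BMP pathway, 0.75 for HIF target genes. The remaining list means had 0.73 for polyol/hexosamine/pentose phosphate pathways, 0.69 for microRNA genes, 0.66 for glucose-induced genes under MondoA and ChREBP and fibrillar collagens and matrix proteins. In the 4 other cases the extreme array was 4.5 g/l replicate 3 for Derl3 (0.63), 4.5 g/l replicate 5 for Arrdc4 (0.75), and 0.3 g/l replicate 2 (0.63) and 4.5 g/l replicate 5 (0.74) for the mean of the heat shock genes. Of 16010 probe sets without a gene name here, 581 changed in limma over all probe sets, 358 higher and 223 lower in 4.5 g/l.

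In 0.3 g/l replicate 4 most gene groups lay near the 4.5 g/l arrays. Its contractile list mean lay 0.375 on the log2 scale below the lowest 4.5 g/l array, 4.07 times the SD of that group. This argues against a 0.3 g/l label on a 4.5 g/l sample like the others measured. Its unfolded protein response and interferon list means, however, lay within the range of the 4.5 g/l arrays. Those arrays also differ among themselves, so a wrongly labelled 4.5 g/l sample of another kind stays open. Mixing of both RNAs at 1 share was also argued against: the share of 4.5 g/l that would give its values had a median of 0.582 over 20 contractile genes (quartiles 0.392 and 0.679) and of 1.06 over 22 unfolded protein response genes (1.01 and 1.11). A culture whose conditions differed from those of the rest of its group may account for it, which was not tested.

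Endothelial markers were lower in 4.5 g/l replicates 4 to 6 than in replicates 1 to 3. All 12 markers above the median level of all genes, of 16 measured, were lower in each of the later-numbered arrays, with a median difference of -0.79 (-1.18 to -0.51), a pattern consistent with fewer endothelial cells there; lower expression per cell stays open. Emcn and Cdh5 had mean log2 values of 11.54 and 10.97 in replicates 1 to 3 and of 11.01 and 10.05 in replicates 4 to 6. The gap in the list mean was 0.700 before and 0.676 after cyclic loess, so a further normalization did not remove it. As cyclic loess ran on values already quantile-normalized, an effect of that first step cannot be excluded. Both sets have 1 label, so the design gives no biological difference to set against these.

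Contractile genes were higher in 4.5 g/l. Whether other cell types took a larger share in 0.3 g/l was not settled. The median log2 difference was -0.0514 for adventitial fibroblast markers, -0.197 for endothelial markers and 0.0139 for macrophage markers. Macrophage markers lie near the floor and cannot decide. The endothelial median pools 4.5 g/l replicates 1 to 3 and 4 to 6, which differ. In 4.5 g/l replicates 1 to 3 the endothelial list means were not below those of 0.3 g/l, while the contractile means were higher. For those arrays this argues against the endothelial share as the whole cause. Fibroblast markers moved apart, with Cd34 falling by 1.02 on the log2 scale and Gsn and Smoc2 rising by 0.83 and 0.68, all 3 named after their values were seen. Their median therefore cannot decide on the fibroblast share. The median of the contractile list was 1.14 before and 1.16 after cyclic loess, so a further normalization did not remove the difference. Cyclic loess ran on values already quantile-normalized, so it cannot exclude an effect of that first step. A response to glucose may account for the difference, and an osmotic effect of the medium stays open.

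Among 100 of the 462 possible splits of the 12 arrays into equal groups, 2 gave at least as many changed genes as the real one, itself included. A count of 3444 was thus rare among regroupings of these arrays. As the arrays may be technical replicates, this cannot exclude a chance difference between the cultures. The highest other split gave 3855 genes and exchanged 0.3 g/l replicate 4 with 4.5 g/l replicate 2. The next gave 2536 and exchanged 0.3 g/l replicate 4 with 4.5 g/l replicate 6, and 96 of the others gave 0. Both splits with many genes moved 0.3 g/l replicate 4, so the count cannot decide on which side that array belongs. For the 18 lists past the camera threshold, 8 of the 100 splits gave as many, the highest of the others 20, so chance was not excluded for that count. The median over the other splits was 8 lists, so passing camera with the preset correlation is weak evidence by itself.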

How the results depend on the processing

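The comparisons within replicates 1 to 3 or 4 to 6, the latter also with 0.3 g/l replicate 4 left out, the block of those number ranges, and the estimated correlation without 0.3 g/l replicate 4 or within replicates 1 to 3 were chosen only after the results were seen. No named gene and no list passed in the opposite direction under any alternative run, and among changed genes shared with the comparison of all arrays 0 were opposite, over the alternatives that test the same genes. All 97 named genes kept their side of the threshold with trend and robust moderation, without the lowest 25% of genes, under each renormalization and under either choice of probe sets. With array weights, 0.3 g/l replicate 4 had a weight of 0.234 and the others 0.864 to 1.52. There 5419 genes passed (2347 higher, 3072 lower) and the camera adjusted p of glycolysis was 0.104. Leaving out that array moved both the same way, to 5295 genes and 0.236. As the other weights varied too, its part in the weighted result was not separated. The exact rank-sum test passed 1993 genes (1028 higher, 965 lower, 458 at least 1.5-fold) and 27 named genes were lost. Testing against a fold of 1.2 passed 454 genes (265 higher, 189 lower, 439 at least 1.5-fold) and 39 named genes were lost, by construction. Leaving out 1 array in turn gave 2514 to 5295 changed genes and 1303 to 3007 lower ones, each highest without 0.3 g/l replicate 4, and adjusted p values of 0.00583 to 0.236 for glycolysis, again highest without that array. Within replicates 1 to 3, the adjusted p of glycolysis was 0.0983 and 6 named genes were lost. Within replicates 4 to 6, 30 genes passed (21 higher, 9 lower, 30 at least 1.5-fold), the adjusted p of glycolysis was 0.0859, and 90 named genes were lost, while the log2 difference was 3.07 for Myh11, against 3.18 over all arrays. With 0.3 g/l replicate 4 left out there, 3435 genes passed (1453 higher, 1982 lower, 1672 at least 1.5-fold), 8 named genes were lost and glycolysis had 0.739, so the low count depended on that array. With an estimated correlation 1 of the 42 lists passed, DNA replication (0.0339), with adjusted p values of 0.177 for the contractile, actin and ATF4 lists, 0.301 for the unfolded protein response and 0.435 for glycolysis. With that and 0.3 g/l replicate 4 left out, 6 lists passed, without DNA replication (0.0555), and glycolysis had 0.668. With that within replicates 1 to 3, 1 list passed, mitosis (0.0420), while DNA replication had 0.196, with 0.0730 for the contractile, ATF4 and unfolded protein response lists, 0.0903 for actin and 0.626 for glycolysis. Where no cause is named, the cause was not tested. With the replicate number as a block (replicate block), 3130 genes passed (1419 higher, 1711 lower), 2827 of them shared; 0 calls of the 97 named genes changed, while immediate early genes (0.0322) and endothelial markers (0.0481) passed. The labels do not say that a number marks a shared origin: deviations of same-numbered arrays correlated by -0.05 to 0.17, and 1 of 6 arrays of 0.3 g/l correlated best with its own number. Dim genes are limited by signal over background, for which no detection call was used here.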

Other observations

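The lists of tRNA synthetases and integrins were chosen only after values of some members were seen; those of vesicle coats and N-glycosylation were written as hypotheses before theirs were seen. Cytosolic tRNA synthetases, which charge tRNAs with amino acids, were lower in 4.5 g/l glucose. Of 18 measured, 13 fell in limma over all genes (15 adjusted over the list alone) and 5 did not pass, with a median log2 difference of -0.53. Wars was 2.98-fold lower, Eprs 1.83-fold, Vars 1.75-fold and Yars 1.73-fold. The camera adjusted p over the 5 added lists was 1.56e-11, and the adjusted p was 0.0828 with an estimated correlation. Since some values were seen before this list was written, these p-values overstate the evidence. Of the 18, 4 also belong to the ATF4 list, Wars among them. Of 16 mitochondrial tRNA synthetases, 1 rose and 2 fell (1 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.134). The difference between both lists was not tested.

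Integrin subunits, which anchor cells to the matrix, rose in 11 and fell in 2 of 17 (12 and 3 adjusted over the list alone; median log2 difference 0.49). Itga5 rose 3.18-fold, Itga8 2.75-fold, Itga1 2.49-fold and Itga9 1.81-fold, whereas Itgb8 was 1.56-fold and Itga4 1.31-fold lower. Camera gave an adjusted p of 2.75e-08 over the 5 added lists, and the adjusted p was 0.0432 with an estimated correlation. As values of some members were seen before the list was written, these p-values overstate the evidence. Of the 17, 3 also belong to other lists. Named after their values were seen, Mir143 and the noncoding RNA Carmn, from the locus of Mir145a, rose 4.13-fold and 4.34-fold (limma adjusted p = 0.00133 and 0.000701), each with overlap between the groups.

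With the unfolded protein response genes lower in 4.5 g/l, other genes of the secretory pathway may be lower too. N-glycosylation and oligosaccharyl transferase genes, which attach sugars to proteins in the endoplasmic reticulum, fell in 18 of 30 (22 adjusted over the list alone; median log2 difference -0.35), with Alg12 2.14-fold, Rpn1 1.75-fold and Magt1 1.61-fold lower. Their camera adjusted p was 8.18e-10, and the adjusted p was 0.0998 with an estimated correlation. Vesicle coat and endoplasmic reticulum export genes fell in 5 of 30 (6 adjusted over the list alone; median log2 difference -0.07), with Mcfd2 1.55-fold and Tmed2 1.25-fold lower. Their camera adjusted p was 0.00483, and the adjusted p was 0.272 with an estimated correlation. Both passed as the hypothesis needs in camera, and neither with an estimated correlation. Over all genes 15.5% changed in either direction, and the vesicle coat median was only -0.07, so that list is weak evidence for the hypothesis.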
